A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

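Per the labels' protocols, total RNA was taken from 50 ml cultures of Saccharomyces cerevisiae BY4741 harvested at mid-exponential phase (OD600 about 0.6), rRNA was removed with Ribo-Zero and libraries were made with standard kits. The series holds 8 libraries, 2 biological replicates of each of 4 groups: inductant 1, inductant 2, naive and vts1 deletion. Per the labels, the inductants had gone through 48 h of VTS1 overexpression from a plasmid that was then removed, followed by passaging for several generations. Groups and replicate numbers were taken from the sample titles.

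The authors quantified each library with kallisto against build R64, per the submitters' processing notes; the kallisto version, the sequencing layout and whether strand was used are not given in the sources used here. The deposited values are, per the file headers, the length, effective length, estimated count and TPM of 6713 open reading frames in each library. The estimated counts deposited by the authors are expected counts from kallisto's assignment of reads to sequences, so they need not be whole; 83.2% to 84.1% of them were whole within 1e-06. The TPM values were also computed by the authors, per the file headers, and rest on the same assignment. Row lengths were multiples of 3 in 99.97% of cases, so they are coding lengths without UTRs, and reads from UTRs were not counted. Effective lengths were the same in all files and differed from the length by 179 in long rows, which means that 1 fixed fragment-length model was used for every library. Because strand is not stated, counting was treated as unstranded: overlapping and antisense genes cannot be told apart, and near-identical copies (Ty elements, ribosomal protein pairs, HXT6 and HXT7, seripauperins) share reads. Rows for rRNA numbered 0, mitochondrial rows 28 and rows of the 2-micron plasmid 4.

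Systematic names were matched to the RefSeq annotation of R64, which gave symbols, products and coordinates to 6026 rows and none to the other 687, which were kept in the tests under their systematic names. Depth ranged from 18431474 to 27501966 estimated counts per library. A count of 0 allows up to 3 counts, which is 0.109 to 0.163 CPM, and the interval for the VTS1 level is an exact 95% one; both cover counting error only.

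Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling (factors 0.946 to 1.093), filterByExpr by group, which kept 6230 genes, and the robust quasi-likelihood test with 1 mean per group and no covariate. All 8 libraries entered 1 model with 4 residual degrees of freedom and a common biological coefficient of variation of 0.096. The spread in this model was that between the 2 cultures of a group. Variation between induction events or between strains did not enter the p-values. The adjusted p-values in the text come from this two-sided test with Benjamini-Hochberg adjustment over the genes tested, and a gene was called changed at an adjusted p under 0.05. Errors of log2 fold changes are standard errors from the fit, and CPM values are scaled with TMM and given as mean ± SD of the replicates. The contrasts were both inductants (equal weights) against naive, the deletion against naive, both inductants against the deletion, each inductant against naive, and inductant 1 against inductant 2.

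Gene lists (31, of which 30 had at least 4 tested members) were written from general knowledge of yeast biology. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists in a comparison, beside camera with an estimated correlation. Every list call was lost with an estimated correlation. The test fry, also planned, asks whether members changed at all rather than more than other genes. Of the lists called in the inductants against naive, only general stress (adjusted p = 0.033), G1/S and G2/M (adjusted p = 0.0115 each) passed fry. Of those called in the deletion against naive, all but ribosome biogenesis (adjusted p = 0.362) passed fry. Results of 1 list and of 1 gene are not reported here. A list's count is given over all genes tested and adjusted over the list alone. Hairpins that Smaug proteins bind were predicted in 6014 annotated coding sequences as the loop C-N-G-G followed by 0 to 3 bases and closed by 5 Watson-Crick pairs on the sense strand. Carriers were compared with other genes in a linear model of the log2 fold change with log2 coding length, GC content and mean log2 CPM, with 95% intervals from 1000 bootstrap resamples over genes and the loop G-G-N-C as a control. Genes are not independent replicates, so these intervals describe the libraries at hand. Correlations between comparisons that share the naive libraries were set beside 50 simulated draws of unchanged groups. These draws gave every group the same spread per gene, so they may understate noise from the shared naive libraries.

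Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule took, among called genes with a mean of at least 5 CPM whose libraries of one side all lay above those of the other, the 12 largest rises and 12 largest falls in each of the main comparisons and 5 and 5 in the others. It also took VTS1, YIR016W, HIS3, LEU2, MET17 and URA3 whatever their values, and up to 4 examples per list: the called members with the largest change, or the member with the smallest p where none was called. Genes outside it are named only where the text says that they were chosen after their values were seen, or as members of a count or set already described.

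Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, a filter of 10 CPM in 2 libraries, limma on log2(TPM + 1) from the deposited TPM, only the libraries compared, the replicate number as a block, a threshold of 1.5-fold, leaving out each library in turn, other stem rules and no covariates. The edgeR step was tested on simulated data drawn from the means and library sizes of the 6230 genes: for the inductants against naive it recovered 75% of genes changed 1.5-fold and 91% of those changed 2-fold, with 7 other genes called, and for the deletion against naive 66% and 86%, with 15 others. A simulated shift of 0.1 for hairpin carriers in the deletion came back as 0.107, and a shift of 0 in the inductants as 0.0034. The simulated groups all had the same spread per gene, whereas the naive pair varied most in the data. Recovery and other calls against naive may therefore differ from these values. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.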

Results

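RNA was sequenced from 8 cultures of budding yeast (Saccharomyces cerevisiae) of the BY4741 background, a laboratory MATa haploid strain that lacks the marker genes LEU2, MET17 and URA3. The cultures belonged to 4 groups of 2 biological replicates each. Vts1, the yeast Smaug protein, binds RNA hairpins through its SAM domain and promotes deadenylation and decay of the bound transcripts. In 2 of the groups, wild-type cells had carried a plasmid that overexpressed VTS1 for 48 h, had lost the plasmid and had then been passaged for several generations. These groups are called inductant 1 and inductant 2, the products of independent inductions of the state named [SMAUG+]. The naive group was wild type without the overexpression, and the deletion group lacked VTS1. Total RNA was depleted of rRNA and sequenced from 50 ml cultures at mid-exponential phase (OD600 about 0.6). Estimated counts summed to 19744518 and 27501966 in the inductant 1 libraries, 23026200 and 20850037 in inductant 2, 21564079 and 24860631 in naive, and 20242426 and 18431474 in the deletion. Between 317 and 336 of the 6713 rows were at 0 in a library. A floor of 3 counts corresponded to 0.109 to 0.163 CPM per library, and floors and counting intervals cover counting error only.

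VTS1 (YOR359W), which in build R64 lies on chromosome XV from 1011189 to 1012760, was read first because it checks the labels. It had 490 and 650 counts in inductant 1, 794 and 594 in inductant 2, 472 and 488 in naive, and 0 and 2 in the deletion. After scaling, the deletion held 0.25% of the naive VTS1 level, with an exact 95% counting interval of 0.0302% to 0.906%. The plasmid was gone at harvest per the labels, and VTS1 in the inductants differed from naive by a log2 fold change of 0.44 ± 0.13 (SE), which did not pass the test (adjusted p = 0.0685). In inductant 2 alone VTS1 rose by 0.64 ± 0.15 (adjusted p = 0.0248). That call was lost without inductant 1 replicate 1 or 2, inductant 2 replicate 1 or naive replicate 2. Inductant 1 alone gave 0.23 ± 0.15 (adjusted p = 0.394). LEU2, MET17 and URA3 were at 0 in all 8 libraries. HIS3, of which this background keeps part, had between 586 and 1606 counts. It did not pass against naive in the inductants (0.51, adjusted p = 0.199) or in the deletion (-0.39, adjusted p = 0.302). PDE2 (YOR360C), the high-affinity cAMP phosphodiesterase gene, lies next to VTS1 on chromosome XV from 1013241 to 1014821 and was singled out after its values were seen. It rose in the deletion by 0.92 ± 0.08 (adjusted p = 3.31e-05), from 62.3 ± 5.4 CPM to 118 ± 2.0 CPM (mean ± SD, n = 2 per group). HAP5, the neighbour on the other side, was at 10.9 CPM in naive and 11.1 CPM in the deletion.

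The 2 libraries of each group differed by more than counting noise, with chi-square per degree of freedom of 20.6 in inductant 1, 12.4 in inductant 2, 55.7 in naive and 5.45 in the deletion. On this measure, which also grows with depth, the naive pair differed most. The first principal component of log2 CPM held 39.9% of the variance and placed the deletion libraries at 27.42 and 26.08 against -15.87 to -0.07 for the other 6. The second held 18.5% and set the naive libraries apart, at -20.11 and -15.43 against 1.8 to 14.08 for the inductants and the deletion.

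The main question of the design was which transcripts differ between cells carrying the induced state and naive cells. The hexose transporter gene HXT7 and genes for general stress defence were among the largest falls in the inductants. HXT7 (chromosome IV, 1154216 to 1155928), whose product has high affinity, fell by 1.49 ± 0.07 on the log2 scale (adjusted p = 1.16e-06), from 946 ± 103 CPM in naive to 408 ± 11 and 277 ± 14 CPM in inductants 1 and 2 (mean ± SD, n = 2 per group). HXT7 shares reads with its near-identical neighbour HXT6, so its exact level is uncertain. CWP1, which encodes a cell wall mannoprotein, fell by 1.84 ± 0.16 (adjusted p = 0.000143). RGI1 (chromosome V, 292066 to 292551), a gene of respiratory growth, fell by 1.74 ± 0.14 (adjusted p = 0.000367), and GSY1 (chromosome VI, 174265 to 176391), a glycogen synthase, by 1.45 ± 0.13 (adjusted p = 0.000564). CTT1 (chromosome VII, 654634 to 656322), the cytosolic catalase, fell by 1.26 ± 0.13 (adjusted p = 0.000603). In the other direction, YOX1, a homeobox repressor of cell cycle genes, rose by 1.15 ± 0.11 (adjusted p = 0.000176), from 8.9 ± 0.7 CPM in naive to 18.2 ± 2.1 and 21.6 ± 1.2 CPM. PCL1 (chromosome XIV, 87897 to 88736), a cyclin of the Pho85 kinase, rose by 0.84 ± 0.10 (adjusted p = 0.000586) and CDC45, needed to start DNA replication, by 0.72 ± 0.09 (adjusted p = 0.0006).

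Across 6230 genes, 534 changed between the inductants and naive at an adjusted p under 0.05, of which 185 were higher and 349 lower. The test measures spread between cultures of a group, not between induction events, so it does not speak for further inductions. The median absolute log2 fold change of the 534 genes was 0.42, and 154 of them, 21 higher and 133 lower, changed by at least 1.5-fold. The count was 277 without inductant 1 replicate 1, 336 without inductant 1 replicate 2, 315 without inductant 2 replicate 1, 339 and 341 without deletion replicates 1 and 2, and 1221 without naive replicate 2. The share of higher genes rose from 34.6% to 49.8% in the fit without naive replicate 2, was 22.5% to 26.2% in the fits without any other library, and was 13.6% among the genes past 1.5-fold. The remaining large falls were YER067C-A at -1.63, YER066C-A at -1.42, TMA10 at -1.40, EGO4 at -1.38, YKR075C at -1.36, YJL107C at -1.36 (it overlaps PRM10, so reads of the pair cannot be told apart) and YNL194C at -1.29. By their names YER067C-A and YER066C-A lie beside RGI1 (YER067W) on the opposite strand, so their falls may not be separate from that of RGI1. Among the largest rises, WSC4, which encodes a cell wall sensor, stood at 0.73 ± 0.09 and YGR079W, of unknown function, at 0.71 ± 0.10. The retrotransposon frame YML045W rose by 1.89 ± 0.21, from 990 ± 288 CPM in naive to 3733 ± 501 and 3620 ± 166 CPM. It overlaps YML045W-A, and Ty copies are near-identical and share reads, so the copy is uncertain. Calls for the rises YMR050C (0.98), YEL076C (0.71), HLR1 (0.70), YPR196W (0.69), MUP1 (0.68) and YMC2 (0.67) were lost in 6, 5, 2, 7, 6 and 1 of the 8 fits that left out 1 library, always including the fit without inductant 1 replicate 1. YIR016W (chromosome IX, 382628 to 383425), a transcript known to be bound and destabilised by Vts1, fell by 0.35 ± 0.10 (adjusted p = 0.0456), a call that held only in the fit without inductant 1 replicate 2 among those with 1 library left out. Inductant 2 alone gave -0.51 ± 0.11 (adjusted p = 0.017, lost without either of its own libraries) and inductant 1 alone -0.19 ± 0.11 (adjusted p = 0.346).

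**Figure D1:**
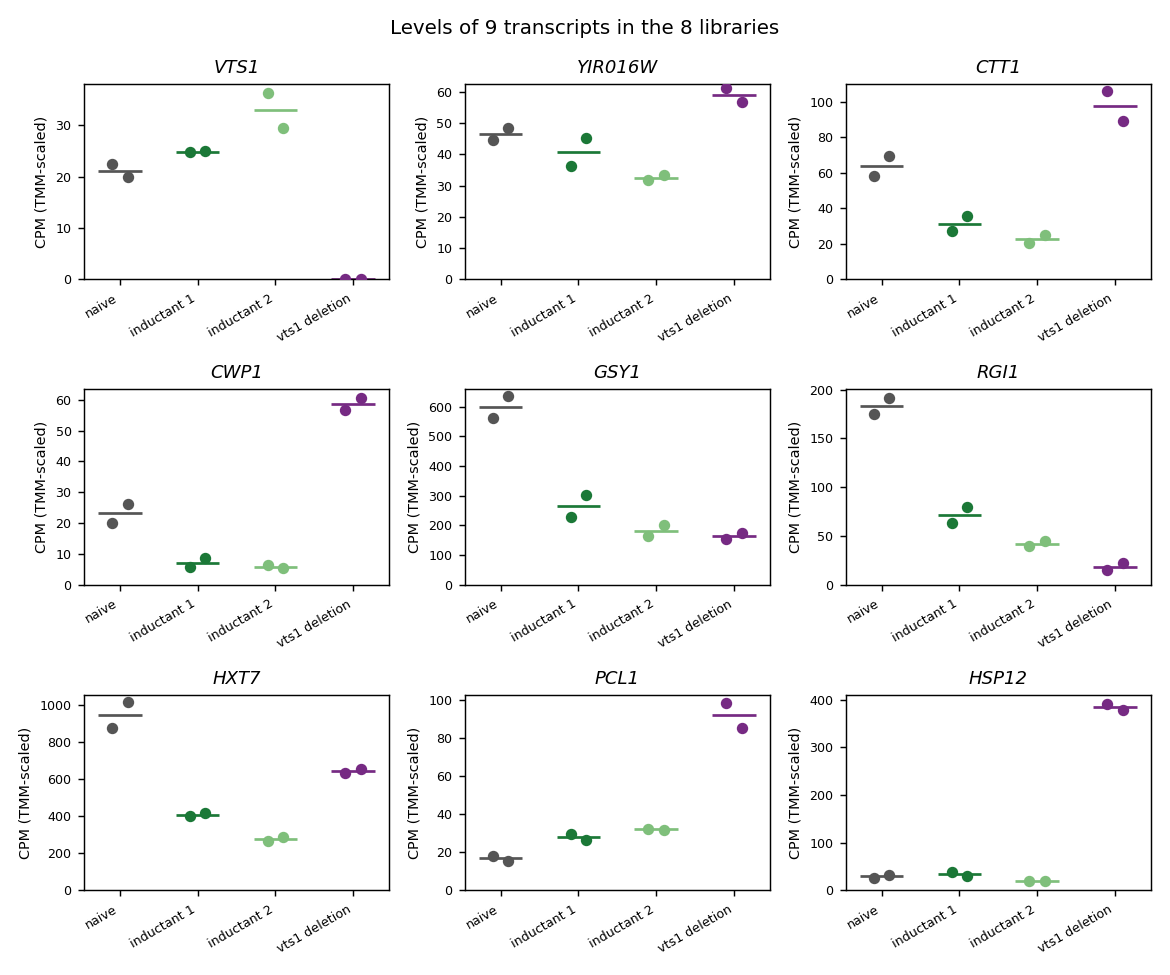
TMM-scaled CPM (vertical axes, starting at 0) of 9 genes in each of the 8 libraries, by group. Points are libraries and the line is the mean of 2. VTS1 is near 0 in the deletion alone, HXT7 falls from 946 CPM in naive to 408 and 277 CPM in the inductants, and HSP12 reaches 385 CPM in the deletion against 29.1 CPM in naive.

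The general stress list, genes induced by many stresses largely through Msn2 and Msn4, moved furthest. Of its 75 members tested 44 fell and 0 rose in the inductants (49 fell and 4 rose adjusted over the list alone), with a median log2 fold change of -0.59. The list had an adjusted p of 2.96e-17 by camera with a preset correlation of 0.01, and an adjusted p of 0.684 with an estimated correlation. GSY1, TMA10 and CTT1 belong to it, as does GPH1, glycogen phosphorylase, at -1.24 ± 0.09. Of 45 genes for hexose transport and glucose repression, 11 fell and 0 rose (15 and 1 adjusted over the list alone). Its members had a median of -0.22 (adjusted p = 0.000705, and adjusted p = 0.684 with an estimated correlation). The falls included HXT7, HXT2 (-0.84 ± 0.08), HXT4 (-0.81 ± 0.08) and MTH1 (-0.82 ± 0.12), a regulator of HXT genes. Without naive replicate 2 the hexose list had a median of -0.092 and an adjusted p of 0.107. Of 135 cytosolic ribosomal protein genes, many of them near-identical pairs that share reads, 22 fell and 0 rose (85 and 0 adjusted over the list alone). Their median was -0.19 (adjusted p = 2.96e-17, and adjusted p = 0.684 with an estimated correlation), with RPL33B at -0.36 ± 0.08, RPL29 at -0.53 ± 0.11 (lost without naive replicate 1) and RPL15A at -0.40 ± 0.08 (lost without inductant 1 replicate 1). Without naive replicate 1 the ribosomal median was -0.12. The number of ribosomal genes called was 3 without naive replicate 1, 4 and 5 without inductant 1 replicates 2 and 1, 7 without inductant 2 replicate 2, 8 without either deletion library and 89 without naive replicate 2.

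Lists of cell cycle genes other than histones rose in the inductants. Of 34 genes peaking at G1/S, 12 rose and 0 fell (18 and 0 adjusted over the list alone). They had a median of 0.23 (adjusted p = 1.30e-08, and adjusted p = 0.339 with an estimated correlation). YOX1, PCL1 and CDC45 belong to it. Leaving out any 1 library other than naive replicate 2 left 6 or 7 of the G1/S genes called. Of 25 genes peaking at G2/M, 5 rose and 1 fell (12 and 1 adjusted over the list alone). The list stood at a median of 0.18 (adjusted p = 8.02e-05, and adjusted p = 0.339 with an estimated correlation). WSC4 was among its rises and NCE102, a protein of membrane eisosomes, was its fall at -0.38 ± 0.07. Of 11 histone genes, 2 fell (5 adjusted over the list alone). The histones had a median of -0.15 (adjusted p = 0.00903, and adjusted p = 0.684 with an estimated correlation). HTA1 stood at -0.48 ± 0.08. The histone list missed the threshold without inductant 1 replicate 2 or naive replicate 1 (adjusted p up to 0.0994), and its median was -0.24 without naive replicate 2.

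Of 62 amino acid biosynthesis genes, 2 rose (TRP5, 0.34, and HIS7, 0.31) and 1 fell (GCV3, -0.34), with 0 called adjusted over the list alone. The list shifted upward as a whole, with a median of 0.20 (adjusted p = 3.10e-06, and adjusted p = 0.684 with an estimated correlation). Its median was 0.066 without naive replicate 1 and 0.32 without naive replicate 2. None of these 3 calls was kept in every fit with 1 library left out: without inductant 1 replicate 1 or 2, inductant 2 replicate 2 or naive replicate 1 all 3 were lost. Sulfur metabolism had 2 of 34 genes higher (2 adjusted over the list alone). They had a median of 0.19 (adjusted p = 0.00646, and adjusted p = 0.684 with an estimated correlation). The genes were MUP1, a methionine permease, and MET5, a subunit of sulfite reductase, at 0.47 ± 0.10. MET5 was lost without either inductant 1 library, and the list itself without naive replicate 1 (median 0.099, adjusted p = 0.219). Of 35 proteasome genes, 2 fell (1 adjusted over the list alone). Their list had a median of -0.10 (adjusted p = 0.00646, and adjusted p = 0.721 with an estimated correlation). RPN4, the transcription factor of the proteasome genes, fell by 0.43 ± 0.07, and PUP3 by 0.21 ± 0.06, a call lost whichever library was left out. The proteasome list missed the threshold without naive replicate 1 (median -0.028, adjusted p = 0.277), and its median was -0.16 without naive replicate 2.

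Several lists did not pass in the inductants as a whole, although single members did. In the cell wall integrity list (32 genes, adjusted p = 0.184) 8 fell and 1 rose, with 10 and 3 adjusted over the list alone. The falls held CWP1, PIR3 (-1.24 ± 0.16), the kinase gene SLT2 (-1.02 ± 0.10) and its target factor RLM1 (-0.65 ± 0.08). In the respiration and TCA list (54 genes, adjusted p = 0.92) 6 fell, with 6 adjusted over the list alone. HAP4, the activating subunit of the HAP complex, was at -1.06 ± 0.08 and the NADH dehydrogenase gene NDI1 at -0.58 ± 0.07. Ribosome biogenesis (adjusted p = 0.317) had 4 of 120 genes higher and 2 adjusted over the list alone, with UTP18 at 0.52 ± 0.08. The pheromone response list (adjusted p = 0.598) had 2 of 29 higher and 2 lower (6 and 4 adjusted over the list alone), with PRM5 at -0.93 ± 0.08. The adhesion list (adjusted p = 0.221) had 2 of 19 higher and 1 lower (3 and 1 adjusted over the list alone), the latter being MGA1 at -1.22 ± 0.17. Heat shock factor targets (adjusted p = 0.706) had 2 of 29 higher and 1 lower (3 and 1 adjusted over the list alone), HSP42 at -0.75 (lost without naive replicate 1). Glycolysis (adjusted p = 0.592) had 1 higher and 3 lower of 25, with 1 and 4 adjusted over the list alone.

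In the smaller sets few members passed. The mitochondrially encoded genes (adjusted p = 0.185) had 1 of 17 lower, with 2 adjusted over the list alone. The zinc regulon (adjusted p = 0.744) had 2 of 15 lower and the phosphate regulon (adjusted p = 0.131) 1 of 20, with 2 and 1 adjusted over the list alone. The iron regulon (adjusted p = 0.317) had 1 higher and 1 lower of 28, and the deadenylation and decapping machinery (adjusted p = 0.878) 1 and 1 of 38, in both cases with 1 and 1 adjusted over the list alone. Meiosis and sporulation (adjusted p = 0.317) had 1 of 55 higher and ergosterol synthesis (adjusted p = 0.598) 1 of 27, with 0 and 1 adjusted over the list alone. The seripauperins (adjusted p = 0.92), a multigene family with shared reads, had 1 of 14 lower and 2 adjusted over the list alone. Translation factors (38 genes, adjusted p = 0.592), the retrograde response (9 genes, adjusted p = 0.92) and the auxotrophic markers (4 genes, adjusted p = 0.317) had 0 called, likewise adjusted over the list alone. MATa-specific genes (5 genes, adjusted p = 0.184) had 0 called and 1 higher adjusted over the list alone. MATalpha-specific genes had too few tested members for a list test. Among them SAG1 differed by 0.25 ± 0.09 (adjusted p = 0.125) and STE3 was at 5.2 CPM in naive and 4.6 and 5.3 CPM in the inductants. In 7 lists that did not pass, the median, the mean and the direction of the test differed in sign: ribosome biogenesis, heat shock, pheromone, respiration, retrograde response, seripauperins and translation.

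Each induction was also compared with naive on its own. Inductant 1 differed in 274 genes (75 higher, 199 lower) and inductant 2 in 563 (202 higher, 361 lower). The excess of lower genes was not stable: without naive replicate 2, higher and lower genes were about equally many in both inductants. HXT7 fell by 1.21 ± 0.08 in inductant 1 and 1.77 ± 0.08 in inductant 2, and RGI1 by 1.36 and 2.13, while YOX1 rose by 1.03 and 1.28 and PCL1 by 0.74 and 0.94. The inductant 1 calls of RGI1 and PCL1 were lost without inductant 1 replicate 1, and that of RGI1 with limma on TPM. General stress genes fell in both, 26 of 75 in inductant 1 and 48 of 75 in inductant 2 (38 and 53 adjusted over the list alone), while 1 and 0 rose (5 and 0 adjusted over the list alone). The list had an adjusted p of 4.27e-08 and 3.03e-25, and an adjusted p of 0.883 and 0.462 with an estimated correlation. The 26 stress genes of inductant 1 were 4 and 11 without its own replicates 1 and 2, and 1 with limma on TPM. Ribosomal protein genes fell in inductant 1, where 55 of 135 were called (126 adjusted over the list alone). The list stood at a median of -0.29 (adjusted p = 3.44e-33, and adjusted p = 0.883 with an estimated correlation). Without either inductant 1 library 0 ribosomal genes were called, 8 and 6 without deletion replicates 1 and 2, 22 without naive replicate 1 and 116 without naive replicate 2. In inductant 2, 0 were called, also adjusted over the list alone, and 23 were called without naive replicate 2, although the list passed with a median of -0.08 (adjusted p = 0.00371, and adjusted p = 0.869 with an estimated correlation). That median was -0.16 and -0.036 without inductant 2 replicates 1 and 2, and -0.0098 and -0.14 without naive replicates 1 and 2. Hexose transport, G2/M and proteasome genes passed as lists in inductant 2 and not in inductant 1. The hexose medians were -0.084 in inductant 1 (adjusted p = 0.174) and -0.32 in inductant 2 (adjusted p = 8.95e-07). Those of G2/M were 0.10 (adjusted p = 0.0787) and 0.27 (adjusted p = 3.80e-07). Those of the proteasome were -0.065 (adjusted p = 0.154) and -0.13 (adjusted p = 0.0006). Histones passed in inductant 1 (adjusted p = 0.00497) and not in inductant 2 (adjusted p = 0.0531). Of the 30 lists tested, 10 passed in inductant 1 and 11 in inductant 2, and 0 in either with an estimated correlation. The inductant 1 count was 24 and 48 without its own replicates 1 and 2, 115 and 107 without deletion replicates 1 and 2, 1048 without naive replicate 2, and 16 with limma on TPM. The inductant 2 count was 161 and 345 without its own replicates and 1023 without naive replicate 2, and replicate numbers used as a block gave 422 genes for inductant 1.

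Changes against naive were related between the inductions. Across 6230 genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.69 and Spearman's rho = 0.661, against a mean r of 0.482 ± 0.077 (SD) in 50 draws of unchanged groups set against the same naive libraries. The covariance was 0.118 against a simulated 0.0368 ± 0.0076, a difference of 0.0815. Both inductions raised 49 genes, where 2.43 would be shared by independent lists, and lowered 109 where 11.5 would be. Opposite calls numbered 0 in both directions, against 4.35 and 6.45 for independent lists. Splitting the naive group would leave 1 library per part, so part of the excess may come from the shared controls. The draws gave every group the same spread per gene, although the naive pair differed most. The simulated r and covariance may therefore be too low. Without naive replicate 2, r was 0.774, and it was lowest, 0.457, without inductant 1 replicate 1.

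The inductions were then set against each other. The mitochondrial protein gene FMP48 (1.10 ± 0.12), the transaldolase gene NQM1 (0.97 ± 0.13), the proline oxidase gene PUT1 (0.91 ± 0.15) and XBP1, a stress-induced repressor (0.83 ± 0.11), were higher in inductant 1, and the cyclin gene CLB1 was lower (-0.57 ± 0.07). HXT7 was higher by 0.56 ± 0.08 (adjusted p = 0.0227) and the disaggregase gene HSP104 by 0.58 ± 0.09 (adjusted p = 0.0385). In all 28 genes differed, 25 higher and 3 lower in inductant 1. That split stayed as uneven with RLE scaling (18 and 3) and without a filter on low counts (32 and 4). It was 114 and 66 with DESeq2, 67 and 46 with only the libraries compared, and 96 and 44 with replicate numbers as a block. General stress genes were higher in inductant 1 as a list, with 8 of 75 called (50 adjusted over the list alone). Its adjusted p was 1.10e-26, and its adjusted p was 0.435 with an estimated correlation. The 8 stress genes were 0 and 1 without inductant 1 replicates 1 and 2, 0 and 13 without inductant 2 replicates 1 and 2, 30 and 32 without naive replicates 1 and 2, 2 without either deletion library, and 30 with replicate numbers as a block. The count of 28 was 1, 5 and 1 without inductant 1 replicates 1 and 2 and inductant 2 replicate 1, 9 and 7 without deletion replicates 1 and 2, 318 and 312 without naive replicates 1 and 2, and 140 with replicate numbers as a block. HXT7, HSP104 and the 5 genes named before them lost their call in at least 3 of the 8 fits with 1 library left out, always including those without either inductant 1 library or inductant 2 replicate 1.

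The deletion was compared with naive to ask which transcripts depend on VTS1. The neighbouring PDE2 also rose in the deletion, and the labels do not say how VTS1 was deleted. Changes that follow from PDE2 cannot be told apart from those that follow from losing VTS1. HSP12, which encodes a small membrane-associated stress protein, rose by 3.72 ± 0.14 on the log2 scale (adjusted p = 4.47e-07), from 29.1 ± 4.4 CPM in naive to 385 ± 10 CPM (mean ± SD, n = 2 per group). The cyclin gene PCL1 rose by 2.46 ± 0.11 (adjusted p = 4.02e-07). TKL2, a transketolase, rose by 2.29 ± 0.18 (adjusted p = 1.41e-05) and PUT4, a proline permease, by 1.90 ± 0.24 (adjusted p = 0.000287). RGI1 fell by 3.30 ± 0.19 (adjusted p = 2.76e-05) and EEB1, an acyltransferase that makes ethyl esters, by 2.78 ± 0.15 (adjusted p = 8.51e-06). LEU1, isopropylmalate isomerase of leucine synthesis, fell by 1.73 ± 0.07 (adjusted p = 1.91e-07), from 849 ± 72 to 256 ± 2.5 CPM. HXT1, a low-affinity hexose transporter, fell by 1.65 ± 0.08 (adjusted p = 4.02e-07). CWP1, which fell in the inductants, rose by 1.34 ± 0.17 (adjusted p = 0.000539) in the deletion. The Vts1 target YIR016W rose by 0.34 ± 0.11 (adjusted p = 0.0419), a call lost in 5 of the 8 fits with 1 library left out (either inductant 2 library, naive replicate 1 or either deletion library).

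In all, 1637 of 6230 genes changed in the deletion, 729 higher and 908 lower. The median absolute log2 fold change of these genes was 0.45, and 523 of them were past 1.5-fold (272 higher, 251 lower). Without deletion replicate 1 or 2 the count was 680 or 714. limma on log2(TPM + 1), which does not use TMM scaling, called 990 higher and 460 lower. The share of higher genes was then 68.3% against 44.5%, with the median of all genes at 0.09 rather than 0. The other large rises were YGR079W at 2.79 ± 0.11, YOR338W at 1.95 ± 0.13, YOX1 at 1.89 ± 0.13, the ribosomal protein gene RPS28B at 1.87 ± 0.17, and HLR1 at 1.87 ± 0.16. ICS2 stood at 1.85 ± 0.11, GND2, a phosphogluconate dehydrogenase, at 1.80 ± 0.14, and CWC2, a splicing factor, at 1.79 ± 0.17. The other large falls were HXT6 (-3.28 ± 0.43, reads shared with HXT7), YOL014W (-3.12), YER066C-A (-2.80, beside RGI1 and perhaps not separate from it), SPG4 (-2.63), EGO4 (-2.26), YMR084W (-2.16), YPR204W (-2.18, lost without naive replicate 2) and YMR085W (-2.13, lost without either deletion library).

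Genes of the G1/S transition and of mitochondrial energy metabolism rose in the deletion. Of 34 G1/S genes 23 rose and 0 fell (26 and 0 adjusted over the list alone). The median of this list was 0.44 (adjusted p = 1.09e-09, and adjusted p = 0.434 with an estimated correlation). Examples were the G1 cyclins CLN1 (1.55 ± 0.07) and PCL2 (1.29 ± 0.12). Without deletion replicates 1 and 2 the number was 15 and 16 rather than 23. Of 54 nuclear genes for respiration and the TCA cycle 35 rose and 2 fell (39 and 2 adjusted over the list alone). Its members had a median of 0.40 (adjusted p = 1.02e-08, and adjusted p = 0.434 with an estimated correlation). INH1, an inhibitor of the ATP synthase, rose by 0.96 ± 0.14 and NDE2 by 0.93 ± 0.15. HAP4, whose product activates many of these genes, fell by 1.24 ± 0.10. Of 17 mitochondrially encoded genes 14 rose and 0 fell (14 and 0 adjusted over the list alone). They had a median of 0.61 (adjusted p = 6.18e-07, and adjusted p = 0.434 with an estimated correlation). COX1 rose by 0.79 ± 0.09 and BI2 by 0.82 ± 0.13. Whether mitochondrial rows share reads was not examined, so the rows called may not be separate transcripts. Mitochondrial rows took 1.14% and 1.19% of all counts in the deletion libraries and 0.619% to 0.731% in the other 6.

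Genes for amino acids, sugars and translation fell in the deletion. Of 62 amino acid biosynthesis genes 28 fell and 3 rose (32 and 3 adjusted over the list alone). The list stood at a median of -0.41 (adjusted p = 2.24e-07, and adjusted p = 0.434 with an estimated correlation). The branched-chain enzymes LEU1, BAT1 (-1.52 ± 0.07) and LEU9 (-1.19 ± 0.11) were at the front. Of 45 hexose transport and glucose repression genes 18 fell and 0 rose (18 and 0 adjusted over the list alone). The median of this list was -0.36 (adjusted p = 2.56e-06, and adjusted p = 0.434 with an estimated correlation). HXT1 and the repressor gene MIG3 (-1.62 ± 0.15) were examples. Of 25 glycolysis and fermentation genes 16 fell and 1 rose (17 and 1 adjusted over the list alone). Its members had a median of -0.33 (adjusted p = 5.51e-06, and adjusted p = 0.434 with an estimated correlation). The hexokinase gene HXK2 stood at -1.16 ± 0.07 and TDH2 at -0.87 ± 0.09. Of 38 translation factors 21 fell and 2 rose (22 and 2 adjusted over the list alone). They had a median of -0.22 (adjusted p = 9.91e-05, and adjusted p = 0.526 with an estimated correlation). Without naive replicate 2 the medians of the amino acid and hexose lists were -0.18 and -0.18, and without naive replicate 1 that of the translation list was -0.14. ANB1, the hypoxic form of eIF5A, was lowest at -1.65 ± 0.19, and SUI1 rose by 0.89 ± 0.15.

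Smaller shifts passed in 7 further lists, and with an estimated correlation none of these calls was kept. Of 19 adhesion and filamentation genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with the signalling mucin MSB2 at 0.77 ± 0.07. That list had an adjusted p of 0.00617, and an adjusted p of 0.434 with an estimated correlation. Of 120 ribosome biogenesis genes 39 fell and 12 rose (45 and 15 adjusted over the list alone), with NOP7 at -0.80 and UTP9 at 1.08. The list stood at a median of -0.16 (adjusted p = 0.00824, and adjusted p = 0.813 with an estimated correlation). Without naive replicate 1 its median was -0.021 and its adjusted p 0.913, and without naive replicate 2 its median was -0.28. Heat shock factor targets had 12 of 29 higher and 4 lower (13 and 5 adjusted over the list alone), including HSP26 (1.62 ± 0.20), SSA4 (1.41 ± 0.08) and HSP82 (1.10 ± 0.11). Their adjusted p was 0.0334, and their adjusted p was 0.728 with an estimated correlation. The heat shock list missed the threshold without inductant 2 replicate 1 or 2, naive replicate 2 or deletion replicate 2 (adjusted p up to 0.169).

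The last 4 of these lists each had an adjusted p of 0.0297, and an adjusted p of 0.434 with an estimated correlation. The G2/M list had 8 of 25 higher and 1 lower, the same counts adjusted over the list alone, with the mitotic cyclin CLB1 at 0.72 ± 0.07. The pheromone list had 11 of 29 higher and 3 lower (13 and 3 adjusted over the list alone), with FAR1, which arrests cells on pheromone, at 1.15 ± 0.09. MATa-specific genes had 4 of 5 higher and 0 lower (4 and 0 adjusted over the list alone), among them STE2, the receptor of alpha-factor, at 0.32 ± 0.07 (lost without either deletion library). Ergosterol synthesis had 3 of 27 higher and 8 lower (3 and 10 adjusted over the list alone), with ECM22, a sterol regulator, at -0.89 ± 0.09. The G2/M call was lost without naive replicate 1 (adjusted p = 0.0657) and the pheromone call without naive replicate 2 (adjusted p = 0.0502). The MATa-specific and ergosterol calls were lost without naive replicate 1 or deletion replicate 1 (adjusted p up to 0.0649 and 0.353). The median of the ergosterol list, -0.09, was -0.17 without naive replicate 2, -0.14 without deletion replicate 2 and 0.0016 on the TPM scale.

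General stress genes moved both ways in the deletion, with 27 of 75 higher and 20 lower (30 and 23 adjusted over the list alone), and the list did not pass (adjusted p = 0.148). Ribosomal protein genes had 7 of 135 higher and 14 lower (3 and 8 adjusted over the list alone), and the list did not pass (adjusted p = 0.215). Their median of -0.05 became 0.05 on the TPM scale and 0.028 without naive replicate 1. The number lower was 3 and 4 without deletion replicates 1 and 2, and 7 and 35 without naive replicates 1 and 2. The cell wall integrity list (adjusted p = 0.32) had 6 of 32 higher and 11 lower (7 and 12 adjusted over the list alone), with CWP1 and TIP1 (1.33 ± 0.11) higher and SLT2 (-1.16 ± 0.12) lower. The iron regulon (adjusted p = 0.0523) had 3 higher and 5 lower (3 and 6 adjusted over the list alone) and sulfur metabolism (adjusted p = 0.1) 1 and 5 (1 and 4 adjusted over the list alone). The zinc regulon (adjusted p = 0.277) had 0 and 3 and the phosphate regulon (adjusted p = 0.516) 4 and 3, the same counts adjusted over the list alone. The retrograde response (adjusted p = 0.0656) had 1 higher and 3 lower (1 and 5 adjusted over the list alone), and holds CIT2 at -2.01 ± 0.28. Seripauperins (adjusted p = 0.175) had 0 higher and 4 lower and histones (adjusted p = 0.904) 1 and 1, the same counts adjusted over the list alone. The proteasome (adjusted p = 0.158) had 5 higher and 0 lower (4 and 0 adjusted over the list alone), and meiosis (adjusted p = 0.468) 4 and 3 (3 and 1 adjusted over the list alone). Deadenylation and decapping (adjusted p = 0.701) had 2 higher and 5 lower (0 and 4 adjusted over the list alone), with a median above 0 and a mean below 0. The markers (adjusted p = 0.841) had 0 called, also adjusted over the list alone. SAG1 differed by 0.21 ± 0.11 (adjusted p = 0.18).

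**Figure D2:**
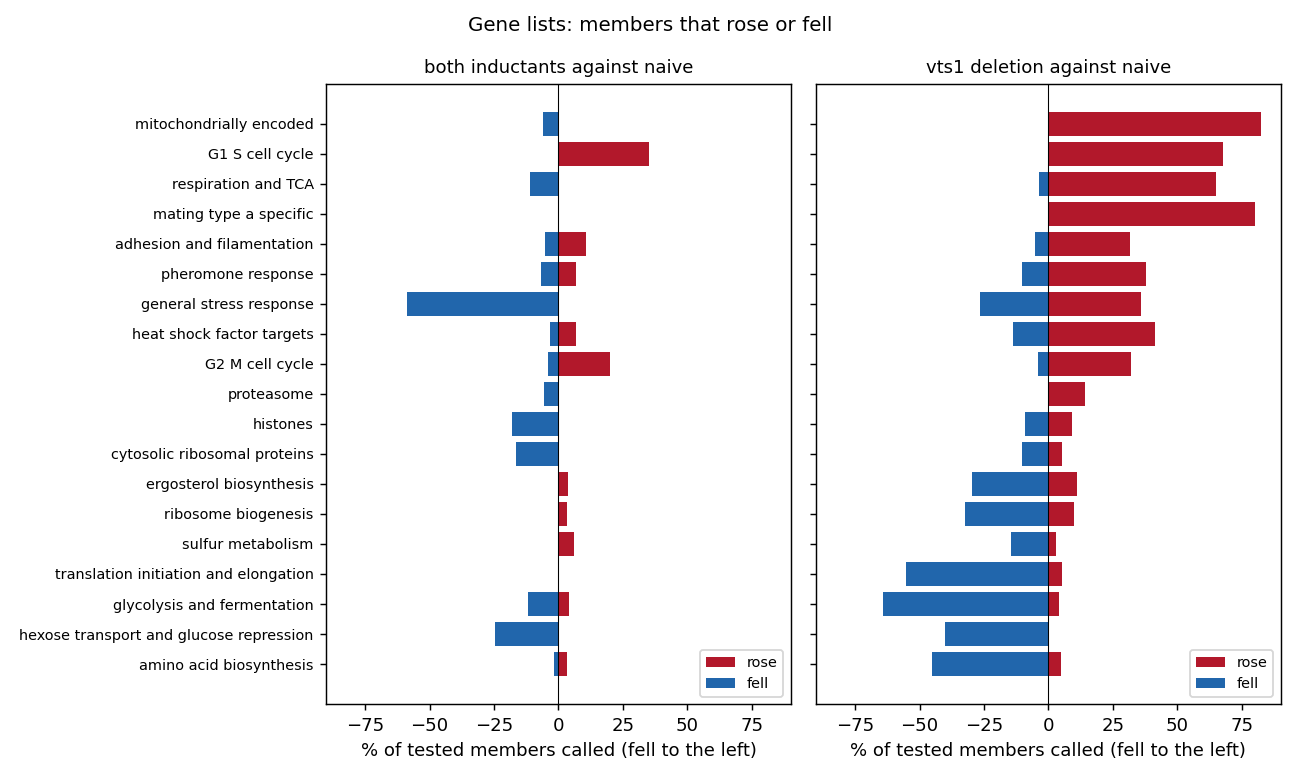
Share of tested members that rose (right, percent) or fell (left, percent) at an adjusted p under 0.05 in the inductants and in the deletion, each against naive, for 19 of the lists called in either comparison. General stress genes fell in 44 of 75 cases in the inductants but went both ways in the deletion (27 higher, 20 lower), and 23 of 34 G1/S genes rose in the deletion against 12 in the inductants.

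Comparing the inductants with the deletion leaves the naive libraries out of the contrast. HSP12 was lower in the inductants, with a log2 difference of -3.89 ± 0.11 (adjusted p = 5.96e-08), as were CWP1 (-3.18 ± 0.15), the aldehyde dehydrogenase genes ALD3 and ALD6 (-2.30 ± 0.09 and -2.02 ± 0.10) and CTT1 (-1.87 ± 0.13). Higher in the inductants were EEB1 (2.80 ± 0.14), IMD2, an IMP dehydrogenase of guanine nucleotide synthesis (2.27 ± 0.09, adjusted p = 5.96e-08), CIT2, the peroxisomal citrate synthase (2.02 ± 0.26), and LEU1 (1.62 ± 0.07). YIR016W was lower in the inductants as well (-0.69 ± 0.09, adjusted p = 0.000272). Of 6230 genes 2344 differed, 1162 higher and 1182 lower in the inductants, and 643 by at least 1.5-fold. Without deletion replicates 1 and 2 the count was 1162 and 1115. Further large differences were VTS1 itself, YOL014W (2.97), ATG41 (2.41), YDL241W (2.25), YPR204W (2.22) and SPG4 (2.11) on the higher side, and PUT4 (-2.09), YGR079W (-2.08), ICS2 (-2.02), RPS28B (-1.99) and NCA3 (-1.91) on the lower side. ARO5 (2.47) and ADH5 (2.05) lost their call without any 1 of the 6 inductant and deletion libraries, and the Ty frame YML045W-A (-6.37 ± 1.69) lost it in every fit with 1 library left out except that without inductant 2 replicate 2.

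Several lists that had moved against naive also differed directly between the inductants and the deletion, though none did with an estimated correlation. General stress genes were lower in the inductants than in the deletion in 49 of 75 cases and higher in 4 (51 and 6 adjusted over the list alone), with a median of -0.56 (adjusted p = 2.02e-11, and adjusted p = 0.50 with an estimated correlation). Amino acid biosynthesis genes were higher in 45 of 62 and lower in 5 (48 and 6 adjusted over the list alone), with a median of 0.61 (adjusted p = 5.23e-12, and adjusted p = 0.50 with an estimated correlation). Respiration genes (adjusted p = 9.90e-08, and adjusted p = 0.50 with an estimated correlation) were lower in 34 of 54 and higher in 3 (36 and 3 adjusted over the list alone). Mitochondrially encoded genes (adjusted p = 9.90e-08, and adjusted p = 0.50 with an estimated correlation) were lower in 15 of 17 (16 adjusted over the list alone). Ribosomal protein genes (adjusted p = 3.32e-05, and adjusted p = 0.668 with an estimated correlation) were lower in 50 of 135 and higher in 3 (51 and 3 adjusted over the list alone), and 19 and 21 were lower without deletion replicates 1 and 2. G1/S genes (adjusted p = 0.00354, and adjusted p = 0.50 with an estimated correlation) were lower in 13 of 34 and higher in 4, the same counts adjusted over the list alone.

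Except for the proteasome, the lists that follow stood higher in the inductants than in the deletion. With an estimated correlation the adjusted p was 0.50 for glycolysis, sulfur, ergosterol and the retrograde response, 0.526 for translation, the proteasome and hexose transport, 0.668 for iron and 0.71 for ribosome biogenesis. Ribosome biogenesis (adjusted p = 0.000361) had 46 higher and 7 lower (47 and 8 adjusted over the list alone). Translation factors (adjusted p = 5.00e-05) had 20 and 2 and sulfur metabolism (adjusted p = 0.000361) 16 and 0, the same counts adjusted over the list alone. Glycolysis (adjusted p = 7.87e-05) had 17 and 2 (17 and 3 adjusted over the list alone) and hexose transport (adjusted p = 0.00755) 11 and 3 (11 and 2 adjusted over the list alone). Ergosterol synthesis (adjusted p = 0.0168) had 13 higher and 3 lower and the retrograde response (adjusted p = 0.0443) 5 and 1, the same counts adjusted over the list alone. Iron (adjusted p = 0.0247) had 11 and 3 (12 and 3 adjusted over the list alone). The proteasome list was lower in the inductants (adjusted p = 0.0023), with 1 gene higher and 13 lower (1 and 14 adjusted over the list alone). The iron call was lost without inductant 1 replicate 2 or deletion replicate 1 (adjusted p up to 0.0606), and the retrograde call without these or inductant 2 replicate 2 (adjusted p up to 0.0805). The G2/M list (adjusted p = 0.981), histones, the pheromone list and adhesion (adjusted p = 0.0607 each) had passed against naive and did not pass camera here. The same held for heat shock factor targets (adjusted p = 0.102) and MATa-specific genes (adjusted p = 0.19). By fry, the pheromone (adjusted p = 0.00707), MATa-specific (adjusted p = 0.0134) and heat shock lists (adjusted p = 0.0205) did pass. In these, 9 of 29, 3 of 5 and 11 of 29 genes were lower in the inductants, and 1, 0 and 3 higher. G2/M (adjusted p = 0.187), histones and adhesion (adjusted p = 0.0574 each) did not pass fry. Of the lists that did not pass camera, meiosis, cell wall integrity and deadenylation had a median, a mean and a camera direction that differed in sign.

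The next comparison asked whether the inductants moved as the deletion did or the other way. Of the genes called against naive in both, 219 moved in the same direction (64 higher, 155 lower) and 54 in opposite directions (18 higher in the inductants and lower in the deletion, 36 the reverse). Independent lists of these sizes would share 21.6 and 50.9 genes in the same direction and 27.0 and 40.8 in opposite directions. Copies with identical values, such as YRF1-1, YRF1-5 and YRF1-8 among the shared rises, were counted separately. RGI1, GSY1, SLT2, HAP4 and PRM5 fell in both and YOX1, PCL1 and WSC4 rose in both, while CWP1 and CTT1 were among those that went opposite ways. Of general stress genes, 18 moved the same way and 11 opposite ways. Across 6230 genes, which are not independent replicates, r was 0.343 (rho = 0.225), below the mean r of 0.573 ± 0.064 (SD) from 50 simulated draws of unchanged groups against the same naive libraries. The covariance was 0.0654 against a simulated 0.0383 ± 0.0071, a difference of 0.0271. The naive group cannot be split into parts of 2 libraries, so part of the excess may come from the shared controls. Here too the draws assumed an equal spread in all groups, so the simulated covariance may be too low. The correlation was 0.554 and 0.557 without naive replicates 1 and 2, and 0.269 and 0.263 without inductant 1 replicate 1 and deletion replicate 2.

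**Figure D3:**
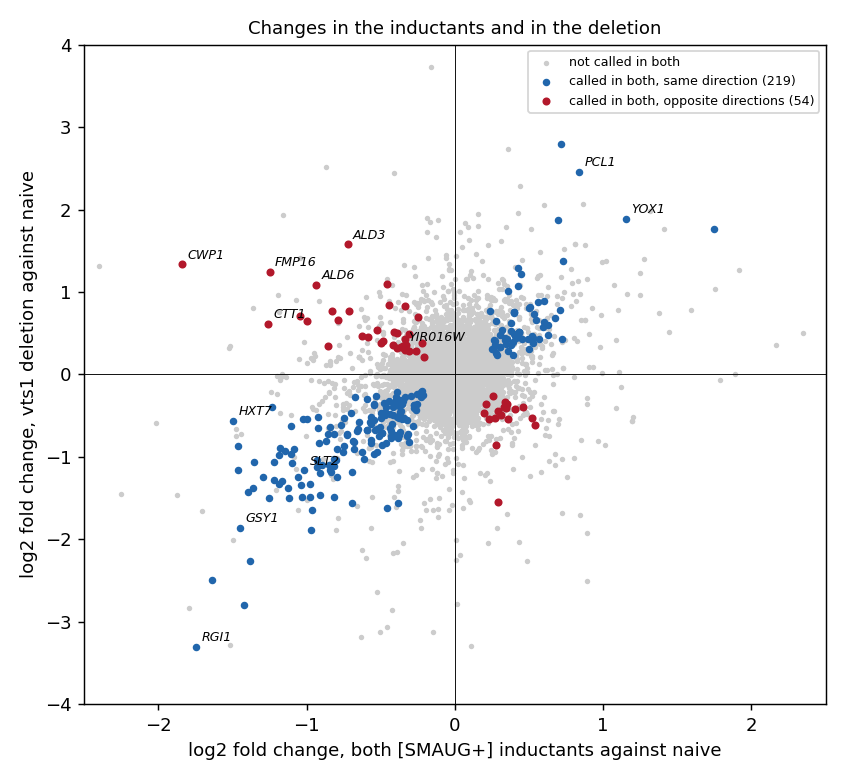
Log2 fold change against naive in the deletion (vertical) and in both inductants together (horizontal) for the tested genes, one point per gene, with the axes limited to 4 and 2.5 and 11 genes outside them. Genes called in both comparisons are coloured, 219 in the same direction in blue and 54 in opposite directions in red.

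Smaug proteins recognise a hairpin with the loop C-N-G-G. Of 6014 coding sequences, 423 held at least 1 such loop closed by 5 Watson-Crick pairs, and 353 held the reversed loop used as a control. In the inductants, genes with the element differed from those without by 0.0015 in mean log2 fold change (95% bootstrap interval -0.0284 to 0.0316), after adjustment for length, GC content and level. In the deletion the difference was 0.0426 (-0.0338 to 0.0987), and the reversed loop gave 0.0296 (-0.013 to 0.0792). None of these intervals excluded 0. The carriers included VTS1, the deleted gene itself. Without it the difference in the deletion was 0.0635 (0.0205 to 0.108), an interval above 0, in a fit chosen after seeing the data. Stems of 4 pairs, of 5 pairs with 1 G-U pair allowed and of 6 pairs gave 0.0416 (0.0087 to 0.075), 0.0425 (0.009 to 0.0752) and 0.1087 (0.0315 to 0.1845), also above 0. With no covariates and VTS1 kept, the difference was 0.0411 (0.0095 to 0.0724) in the inductants, an interval above 0, and 0.0111 (-0.0623 to 0.0697) in the deletion. Without naive replicate 1 it was 0.0195 (-0.0601 to 0.0817) in the deletion. As a list, element carriers had 27 of 419 genes higher and 23 lower in the inductants (42 and 30 adjusted over the list alone), and the list did not pass (adjusted p = 0.0927). In the deletion they had 85 higher and 70 lower (95 and 81 adjusted over the list alone), and again the list did not pass (adjusted p = 0.495). GSY1, YKR075C, TPS2 (-1.18 ± 0.09), a trehalose phosphate phosphatase, and HAP4 carried the element and fell in the inductants, and all 4 fell in the deletion too (-1.86, -1.37, -0.89 and -1.24). PCL1 and WSC4 carried it and rose in both comparisons, and the carrier YOR338W rose in the deletion and stood at 0.16 (adjusted p = 0.407) in the inductants.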

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

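The tests on whether all naive cultures stood apart and on the mitochondrial rows with most reads were chosen only after the results they bear on were seen; the other tests in this part were fixed before.

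The inductions, labelled as independent products of the same treatment, differed from each other in 28 genes by a direct test of the difference (inductant 1 minus inductant 2). The named genes were FMP48 (1.0989), NQM1 (0.9667), PUT1 (0.9093), XBP1 (0.8331), YCL042W (0.7965, a frame that overlaps the glucokinase gene GLK1), CLB1 (-0.5659), ILV5 (-0.4648) and KAP122 (-0.4255). The count was 1 without inductant 1 replicate 1 or inductant 2 replicate 1, 5 without inductant 1 replicate 2, 9 and 7 without deletion replicates 1 and 2, and 318 and 312 without naive replicates 1 and 2. By list, median log2 differences were higher in inductant 1 for general stress (0.4417), hexose transport (0.2382), respiration (0.2073), heat shock (0.1206) and proteasome genes (0.0607). They were lower for mitochondrially encoded genes (-0.2579), ribosomal proteins (-0.2272), MATa-specific genes (-0.2143), G2/M (-0.1875), phosphate (-0.1758), pheromone (-0.1222), ribosome biogenesis (-0.1146) and translation (-0.0671). These 13 lists passed with a preset correlation and 0 did with an estimated one (adjusted p = 0.435 for general stress and 0.533 for ribosomal proteins).

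General stress genes were lower in the inductants than in naive, 44 of 75 by the test. A single odd naive library as the source is argued against by the members called lower with 1 of these libraries left out, 38 (with 5 higher) without naive replicate 2 and 46 (with 0 higher) without naive replicate 1. Naive cultures that differed from all others stay open as a source. In a contrast that leaves out the naive libraries, 49 members were lower in the inductants than in the deletion. A fit on only the libraries compared gave 52. The deletion changed this list itself (27 higher and 20 lower against naive), so these counts cannot decide the question. Of the stress genes called against naive in both comparisons, 18 moved the same way and 11 opposite ways. Uneven harvest stage between cultures stays open, since the median difference between the 2 libraries of a group reached 0.218 in naive and 0.194 in inductant 2, which lies between the bounds set for it. A change brought by the induced state, the difference the design names, is among the open explanations and was not tested apart from culture history.

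Genes that changed in both the inductants and the deletion moved the same way in 219 cases and opposite ways in 54. Chance deviations of the shared naive libraries cannot be told apart from a shared response: with naive replicate 1 used for the inductants and replicate 2 for the deletion the covariance over 5029 genes was -0.00807, and 0.0288 with the libraries exchanged, against a simulated SD of 0.0041. Naive cultures that differed from all others stay open too, because 64 of the 219 genes differed between inductants and deletion in the direct test and the rest did not pass it. A response shared by cells that carry the induced state and cells without VTS1 may account for part of the 219 and was not tested in any comparison free of naive libraries.

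Mitochondrially encoded transcripts were higher in the deletion than in naive, 14 of 17 by the test. The 3 rows with most reads (AI1, AI2 and COX1) held 69.2% of mitochondrial reads. With these left out, 11 of the other 14 rows were called higher, so the calls were not confined to these 3 rows. Whether the remaining rows share reads with them or with each other was not examined, so they may not be separate transcripts. With 14 of 17 called, leaving out any 3 rows had to leave at least 11. That count is therefore no separate test of a few abundant rows as the source. GC bias between libraries could contribute and cannot be told apart: the tenth of nuclear genes with the lowest GC content, 573 genes with a median GC of 35.3%, had a median of 0.096 (0.077 to 0.127), but mitochondrial genes have a median GC of 23.2%, beyond the range that nuclear genes cover. An effect of losing VTS1 on mitochondrial transcripts stays among the open explanations, untested.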

How the results depend on the processing

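The SRE difference without VTS1 itself was added after the data were seen; all other settings here were fixed before. With 2 libraries per group and 4 residual degrees of freedom the counts of changed genes move widely. Called directions changed in 0 of the 539 results for named genes under the settings counted next. They changed in 0 of the 40 list calls with RLE scaling, without a filter, with the replicate block or with 1 library left out; with limma on TPM the median of the ergosterol list in the deletion went from -0.09 to 0.0016. Calls of named genes were lost in 6 results with RLE scaling, 10 without a filter on low counts (2 gained), 11 with DESeq2 (19 gained), 145 with limma on TPM (1 gained) and 38 to 143 when 1 library was left out. Of named calls in the inductants, 37 of 86 held in every fit with 1 library left out, against 87 of 122 in the deletion and 98 of 128 between inductants and deletion. It was 7 of 57 for inductant 1, 30 of 76 for inductant 2 and 0 of 13 between the inductants. A lone library of a group was then assumed to vary like the other groups. The cause of the differences below was not tested, except that fits on fewer libraries have fewer degrees of freedom and a fold threshold calls fewer genes by construction. All groups shared 1 estimate of the spread, although the naive pair differed most (chi-square per degree of freedom 55.7 against 5.45 to 20.6). Inductant 1 against inductant 2 went from 28 genes to 113 with only the libraries compared. Adjusted p-values against naive may therefore be too small, and those between other groups too large. Effective lengths were the same in all files, so a length offset changes nothing, and with 0 rRNA rows the setting that keeps them could not be run. Depth limits genes near 0.109 to 0.163 CPM, and recovery on simulated data (75% at 1.5-fold in the inductants) limits small changes.

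For the inductants against naive (534 genes) the count was 248 with limma on TPM, 340 with only the libraries compared, 154 at 1.5-fold and 277 to 1221 with 1 library left out. For the deletion against naive (1637) it was 523 at 1.5-fold and 680 to 1819 with 1 library left out, and for the inductants against the deletion (2344) 643 and 1115 to 2768. Inductant 1 (274) gave 486 with DESeq2, 16 with limma, 109 with only the libraries compared, 87 at 1.5-fold and 24 to 1048 with 1 library left out. Inductant 2 (563) gave 247 with limma, 231 with only the libraries compared, 222 at 1.5-fold and 161 to 1023. Inductant 1 against inductant 2 (28) gave 180 with DESeq2, 2 with limma, 113 with only the libraries compared, 12 at 1.5-fold and 1 to 318. The fits without naive replicate 2 gave the highest or nearly the highest count in each comparison that uses naive except the deletion's, where naive replicate 1 did.

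The correlation of inductant and deletion effects (0.343) was 0.424 without a filter, 0.241 at 10 CPM and 0.263 to 0.557 with 1 library left out, and that of the inductions (0.69) was 0.457 to 0.774. With an estimated correlation camera called 0, 0 and 0 lists rather than 10, 14 and 16. The SRE difference in the inductants was 0.0411 (0.0095 to 0.0724) with no covariates, where the interval excluded 0, and that in the deletion (0.0426) was 0.0416 with 4 pairs, 0.0425 with 1 G-U pair allowed, 0.1087 with 6 pairs and 0.0635 without VTS1, each with an interval above 0. It was 0.0111 with no covariates and 0.0195 without naive replicate 1, with intervals that held 0.

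Over all genes tested, replicate numbers showed no clear pairing: same-numbered deviations correlated at -0.017, -0.113, 0.088, 0.112, -0.045 and 0.072. The general stress list lay lower in replicate 1 than in replicate 2 of each group. Its median differences were -0.045 and -0.194 in inductants 1 and 2, -0.218 in naive and -0.054 in the deletion. A replicate effect shared by the groups therefore stays open for that list. Used as a block, replicate numbers gave 422 genes for inductant 1 and 140 for inductant 1 against inductant 2. The other comparisons gave 647, 1743, 2454 and 627, within 1.5 times.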

Other observations

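The test of the hairpin among genes that rose in the deletion was chosen only after the count of rising carriers was seen, and the summed transposon counts were chosen after single rows were seen; the test on opposite changes was fixed before.

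Retrotransposon rows were a large part of the libraries. The 91 rows whose product is a Gag or Gag-Pol protein summed to 133000 ± 19600 CPM in inductant 1, 132900 ± 252 in inductant 2, 117400 ± 10700 in naive and 93900 ± 1980 in the deletion (mean ± SD, n = 2 per group; not tested as a sum). Of the 73 such rows tested, 5 rose and 0 fell in the inductants, and copies share reads, so single elements are uncertain. YML045W was at 3379 to 4087 CPM in the inductant libraries, 786 and 1193 CPM in naive, and 1092 and 903 CPM in the deletion.

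Smaug proteins promote the decay of hairpin-carrying transcripts, so a hypothesis is that carriers rise when VTS1 is lost. Among scanned genes other than VTS1, 85 of 706 that rose in the deletion carried the C-N-G-G hairpin (12%) against 6.61% of the others (Fisher's exact test, p = 1.28e-06, two-sided; 9.45e-06 adjusted over 10 tests in this family). The reversed loop was carried by 7.22% against 5.92% (Fisher's exact test, p = 0.178; adjusted 0.356). In a logistic model with length, GC content and level, added after the first result, the odds ratio was 1.87 (1.45 to 2.43) for the hairpin and 1.18 (0.864 to 1.61) for the reversed loop; the loops were not tested against each other. PCL1, YOR338W, WSC4, OPY1 and CTR1 were among the carriers that rose. Near-identical copies were counted as separate genes: YRF1-3, a carrier that rose by 0.7633, had the same value as YRF1-7. The p-values of the Fisher and logistic tests may therefore be too small. The comparison of means fixed beforehand, which counts VTS1 itself as a carrier, did not exclude 0 (0.0426, -0.0338 to 0.0987). Without VTS1, as in the tests above, it did (0.0635, 0.0205 to 0.108; chosen after seeing the data). With VTS1 kept among the genes scanned it did with stems of 4 or 6 pairs or with a G-U pair allowed, and did not with no covariates (0.0111). Decay of carriers through Vts1 may contribute; the enrichment was found and tested on the same libraries, so this stays a hypothesis. Genes that fell in the deletion carried the hairpin in 7.75% of cases against 7.19% (Fisher's exact test, p = 0.574), and the reversed loop in 5.51% against 6.18% (p = 0.492). For the reversed loop among these genes the logistic model gave an odds ratio of 0.672 (0.484 to 0.933). That interval lies below 1, and its test did not pass after adjustment over the family.

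A second hypothesis was that the induced state acts on the same transcripts more strongly, so that genes lower in the inductants and higher in the deletion carry the hairpin more often. Of 35 such genes 3 carried it, 8.57% against 7.27% of the others (Fisher's exact test, p = 0.739, two-sided), and 4 carried the reversed loop, 11.4% against 6.05% (Fisher's exact test, p = 0.161, adjusted 0.356), a set too small to decide.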
